A study of Mus musculus and Macaca fascicularis with 152 samples.

How the data were processed

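SC3-seq libraries of 152 single cells, 128 of mouse and 24 of cynomolgus monkey, were analysed from 304 deposited files, 2 per cell. The authors deposited a count file per cell, with the count of reads for each gene, and an RPM file per cell, with scaled values for each gene. The submitters' processing notes name cutadapt 1.3, TopHat 1.4.1, Cufflinks 2.2.0 and HTSeq 0.9.1, and the genome mm10 for all 152 samples, the monkey cells included. The names of the monkey files carry macFas5 instead. The annotation and the use of strand in counting are not stated. The deposited count values were whole numbers and served as the main values, and the deposited RPM values served as an alternative. Within a cell the rank correlation of both across genes had a median of 0.925 and a lowest value of 0.860. Division by the total of a cell would leave the ranks as they are, so the RPM values are not these counts rescaled. No pair of the 304 files was identical.

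The mouse files list 34896 genes and the monkey files 26376. Entries were left out where a value or the symbol was missing, the Entrez identifier was not a plain number, or the names in the count and RPM files differed. They numbered 226 in mouse, 214 of them with a missing count, and 154 in monkey, 153 of them with a missing count. They held 0.000104% and 0.0115% of the counts, so that 34670 and 26222 genes were used. Gene positions are those of a RefSeq gene annotation of GRCm38 (mm10), matched by Entrez identifier, with starts counted from 1. No monkey positions are given. The depth per cell was 378322 to 3622298 counts.

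Cells were grouped by the stage and cell type of their labels. The labels carry 13 codes that begin with MS, 8 of which occur at more than 1 stage, so a code is not an embryo, and its meaning is not given. The headings of the value columns fall into 9 series, here called column series, and no series holds cells of more than 1 mouse stage. As no animal is named, each group was treated as 1 sample, and no p-value, standard error or count of changed genes over the genome was computed. The 1 mGPCs cell of E9.5, the 1 of E11.5 and the 2 mpGrL cells of E13.5 were left out of the comparisons and are given on their own.

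For each comparison the counts were summed over the cells of a group, expressed as CPM, and compared as the log2 ratio of CPM + 1. Intervals of a level are exact Poisson intervals of the sum at 95%. Where a group had no count, the fold is a bound computed from 3 counts over that group. Where it had 1 to 3 counts, levels or counts are given in place of a fold. The chance that a cell of 1 group exceeds a cell of the other (the area under the ROC curve, AUC) describes the overlap of the cells. Cells were also thinned to 400000 counts to compare numbers of detected genes, and 1 monkey cell lay below that depth.

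A gene was named where the mean of both levels was at least 20 CPM, the log2 ratio at least 1 in size, the AUC at least 0.8 and the direction the same within every label code with at least 2 cells of each group. The 10 largest in each direction were named, and predicted or clone names were passed over. With 2 cPGCs an AUC of 1 was needed. From each list described, the 3 members with the largest log2 ratios were eligible for naming as well. The lists count 32, with 337 genes, of which 331 were found in the mouse files and 295 in the monkey files. A list gene was measured where the mean level was at least 5 CPM, and was counted as higher or lower where the log2 ratio was at least 1 in size and the AUC at least 0.65. The median log2 ratio of a list was set against 10000 random lists of the same size, matched in 20 bins of level, and the range that holds 95% of them is given as a description. These rules, the comparisons, the lists and most alternatives were fixed before the data were examined. Which lists the text describes, and which further list members it names, was chosen after the values were seen. Some genes that met these rules are not reported here, while the counts and medians of lists include all measured members.

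The alternatives were TMM factors (edgeR 4.0.16) and DESeq2 1.42.0 size factors in R 4.3.3, the RPM values, equal weights per cell, the mean over cells of log2(CPM + 1), pseudocounts of 0.1 and 10 CPM, no filter or a filter of 20 CPM, no AUC rule, a log2 ratio of at least 2, thinned cells, the comparison within label codes, and leaving out the deepest cell of each group or each label code in turn. Leaving out each column series in turn, and leaving out the 4 cells with at least 1000 CPM of endothelium or red blood cell genes, were added after the data were seen. List medians of the alternatives are set against the random lists of the main comparison. No range was drawn for subsets of cells, where fewer cells may widen it. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

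The rules were tested on simulated data of the same numbers of cells. The first version of that test required a list of 30 genes changed 2-fold to lie above 97.5% of the random lists in every comparison, and it failed for cPGCs against cGPCs. The requirement was then reset to recovery of lists changed 8-fold, of the size of 4-fold changes and of unchanged lists within the random range, and the 2-fold result is given here instead. The simulation used negative binomial counts, with 200 changed genes in each comparison. The spread of each gene was taken over the cells of both groups together, so real differences between groups entered the noise. No effect of label code, column series or animal was simulated. The shares below are thus not error rates of the real comparisons. Unchanged genes met the list rule in 7.61% of cases for E10.5 mGPCs against E9.5 mPIM, in 11.9% for E10.5 mpGrE against mGPCs, in 6.11% for E11.5 against E10.5 mpGrE and in 2.15% for E11.5 mpGrL against mpGrE. The share was 13.6% for E10.5 mST against mpGrE, 20.3% for E11.5 mST against mpGrE, 18.6% for E13.5 against E10.5 mST and 36.2% for cPGCs against cGPCs. In the same order, genes changed 4-fold met the rule in 82%, 78%, 74%, 50%, 66%, 58%, 62% and 50% of cases, and genes changed 2-fold in 30%, 40%, 28%, 22%, 36%, 30%, 34% and 30%. Lists of 12 genes changed 2-fold lay at percentile 34.3 of the random lists for E11.5 mST and 65.6 for cPGCs, and at 99.3 to 100 in the other comparisons.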

Results

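The RNA of 152 single cells was profiled by SC3-seq, a method that sequences the 3′ ends of cDNA amplified from 1 cell. Mouse embryos gave 128 cells and cynomolgus monkey embryos gave 24. The labels sort the cells into 13 groups by stage and by a cell-type abbreviation that they do not spell out. E9.5 held 24 mPIM cells and 1 mGPCs cell from embryo tissue labelled Wt1+. E10.5 female genital ridge held 9 mGPCs, 13 mpGrE and 8 mST cells. E11.5 fetal ovary held 28 mpGrE, 29 mpGrL, 4 mST and 1 mGPCs cells, and E13.5 fetal ovary held 9 mST and 2 mpGrL cells. The E36 female genital ridge of the monkey held 22 cGPCs and 2 cPGCs.

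Each cell carried 378322 to 3622298 counts assigned to genes, with a median of 1024815.5. The labels name no animal, so each group counts as 1 sample, there are no replicates, and no test between groups was made. Levels are given as CPM, the counts of a gene scaled to the summed counts of a group. Their 95% intervals and floors cover counting error only, because PCR reads without molecular identifiers are not independent molecules. The way cells were assigned to types is not given in the labels. Where it used these transcriptomes, the genes that define a type are not independent evidence for it.

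**Figure D1:**
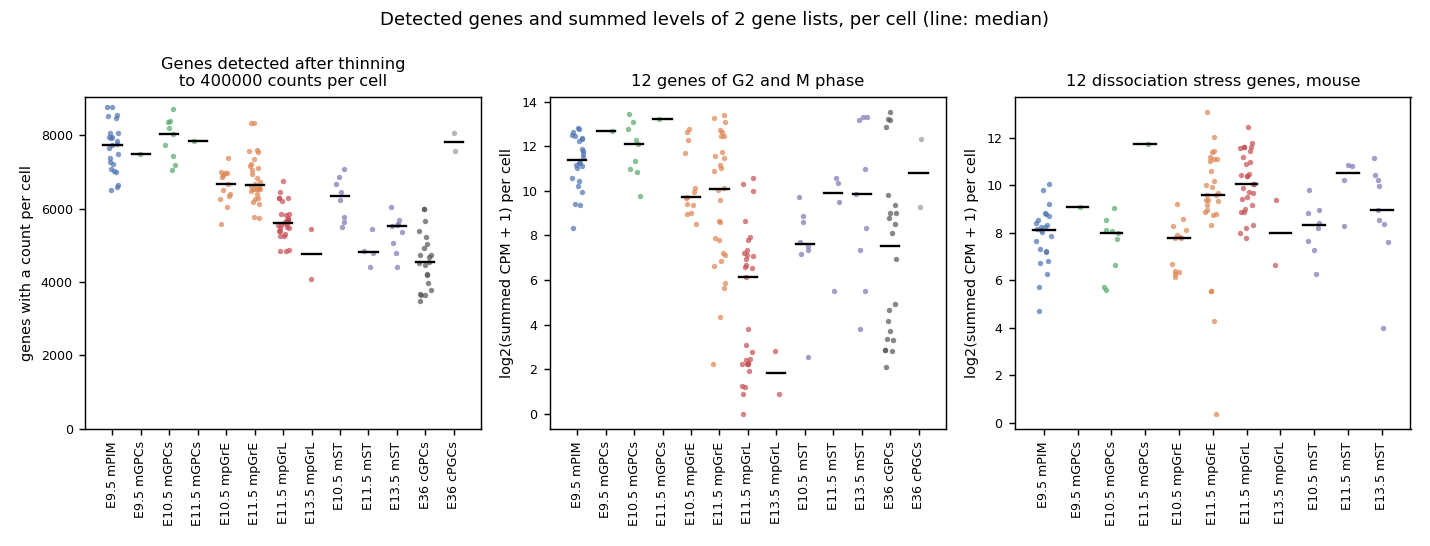
Genes with a count after each cell was thinned to 400000 counts (left), and the summed CPM per cell of 12 genes of G2 and M phase (middle) and of 12 dissociation stress genes in mouse cells (right) on log2 axes with 1 CPM added. Points are cells and lines are medians by group. The E11.5 mpGrL cells have a median of 5608 genes and of 68.2 CPM for the G2 and M phase genes, against 6649 genes and 1088 CPM in the E11.5 mpGrE cells.

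The comparison of E10.5 mGPCs with E9.5 mPIM cells asked which genes differed between the earliest group and the next cell type in stage order. Sall1, a zinc-finger transcription factor needed for kidney development (Entrez 58198; mm10 chromosome 8, 89027242 to 89044162), was at 187.1 CPM (182 to 191.9) in mPIM cells, with counts in 24 of 24. In mGPCs it was at 0.246 CPM (0.0298 to 0.890), from 2 counts in 2 of 9 cells. Gata4, a transcription factor required to form the genital ridge (Entrez 14463; chromosome 14, 63198914 to 63271712), was at 125.5 CPM in mGPCs with counts in 9 of 9 cells. It was at 3.81 CPM in mPIM cells with counts in 2 of 24, a log2 ratio of 4.72.

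Nfib, which encodes a nuclear factor I protein, led the genes higher in mGPCs, at 312 CPM (300.4 to 325) against 0.508 CPM (0.290 to 0.824), a log2 ratio of 7.70. The other named genes on that side were Zfpm2, a cofactor of GATA factors, and Tmtc2, Lama2, Rgs5, Il2rg, Fam19a2, Ppp1r13b, Gucy1a3 and Ecm1. They lay at 56.9 CPM (Il2rg) to 166 CPM (Ecm1) in mGPCs and at 0 CPM (Il2rg) to 2.35 CPM (Ecm1) in mPIM cells. Il2rg had no count in 24 mPIM cells and was at least 598-fold higher in mGPCs, with the floor set at 3 counts over the mPIM group. The genes lower in mGPCs included Eya1, a transcriptional cofactor in early kidney, at 176 CPM (172 to 181) in mPIM cells against 1 count in 9 mGPCs. Magel2, Rdh10, Tmem132c, Xpo5 and Arg1 were lower as well, and so were Hoxb1 and Hoxb5os. Hoxb1 had no count in 9 mGPCs and was at least 168-fold lower there than its 62.2 CPM in mPIM cells. Hoxb5os overlaps its neighbours on the other strand, and the use of strand in counting is not stated, so its value is uncertain.

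Of 14 measured gonadal stroma genes, 8 were higher in mGPCs and 0 lower, with a median log2 ratio of 2.05 (level-matched random lists, −0.39 to 0.39). Postn, a matrix protein, was at 248 against 8.60 CPM and Ptn, a growth factor, at 303 against 32.7 CPM. All 4 measured genes of the pluripotency and reprogramming list were lower, with a median of −2.72 (random lists, −0.79 to 1.08). They were Sall4 (3.45 against 131 CPM), Lin28a (6.65 against 51.9 CPM), Lin28b (20.1 against 131 CPM) and Mycn. The posterior Hox list had a median of −1.75, with 0 genes higher and 4 lower of 13. That median ran from −3.40 to −0.14 over all settings tried, and −0.14 lies inside the range of random lists (−0.49 to 0.81). Hoxa9, Hoxb8, Hoxb9 and Hoxc9 met the rule for list genes. Hoxc10, Hoxa10 and Hoxd10 had the largest log2 ratios of the list (−4.91, −4.80 and −3.79) but counts in 7, 6 and 5 of 24 mPIM cells, and did not meet the part of the rule on overlap between cells.

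Genital ridge factors went both ways, with 4 higher, 2 lower and a median of −0.03 over 12 measured genes. Lhx9 (120 against 0.159 CPM), Gata4, Nr5a1 and Tcf21 were higher, and the genes that were lower included Six4. Lhx9 and Nr5a1, transcription factors of the early gonad, had counts in 5 of 9 mGPCs each. Of 12 measured genes of epithelial to mesenchymal transition, 5 were higher, with a median of 0.84, among them Zeb2 (161 against 39.7 CPM), Vim (1406 against 419.8 CPM) and Twist1 (a log2 ratio of 1.60). The BMP response list had 3 of 7 higher and a median of 0.91, led by Bambi (2.24). The extracellular matrix list had 6 of 14 higher, 2 lower and a median of 0.62, with Tnc at 4.47, Bgn at 4.07 and Sparc at 3.09. Among 13 measured imprinted genes 3 were higher (Cdkn1c 1.77, Plagl1 1.33 and Dlk1 1.24) and the median was 0.40. The WNT response list had 3 of 5 lower, with a median of −1.24 and Lef1 at −2.35 and Tcf7 at −1.24. Glycolysis genes had 4 of 15 lower, a median of −0.55, and Ldha at 526 against 1427 CPM.

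Among lists of other cell types, the red blood cell list had 4 of 7 higher and a median of 3.12, and mGPCs cell 2 held 8310 CPM of its genes. Its median was 1.01 without code MS155 and 1.61 without the cells rich in endothelium or red blood cell genes, where the log2 ratios of Hbb-y and Hbb-bh1 were −3.53 and −3.83. The endothelium list had a median of 4.39, but only 1 of its 5 measured genes, Egfl7, met the rule, and mGPCs cell 9 held 91.8% of its counts. Over all lists, 39 of 233 measured genes were higher and 29 lower, and in simulated data of this size 7.61% of unchanged genes met the same rule. That share, like those given for the other comparisons, covers no effect of code, series or animal and is not an error rate. Scaling by TMM or by DESeq2 size factors shifted all log2 ratios of this comparison by −0.18 or −0.15. The stages share no column series, as the first parts of the value columns' headings are called here, whose meaning is not given, so stage and series cannot be told apart. The label code MS134 holds 5 mGPCs and 3 mPIM cells. Within it the stroma list had a median of 2.68, the pluripotency and reprogramming list of −2.70 and the posterior Hox list of −3.40, and 47 list genes were lower. The extracellular matrix median was 0.088 and the glycolysis median −0.37 there, both inside the range of random lists drawn for all cells. With 1 label code left out, other medians also fell inside that range, namely those of epithelial to mesenchymal transition (0.44) and imprinted genes (0.13) without MS134, and those of the BMP response (0.43), the WNT response (−0.94) and the extracellular matrix (0.34) without MS155. Without the series that held 13 mPIM cells the posterior Hox median was −0.54 and the stroma median 1.305, with Hoxc10 at −0.74 and Hoxa10 at −0.48. Without code MS134 the log2 ratio of Nr5a1 was −0.050 and that of Twist1 was −0.94.

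**Figure D2:**
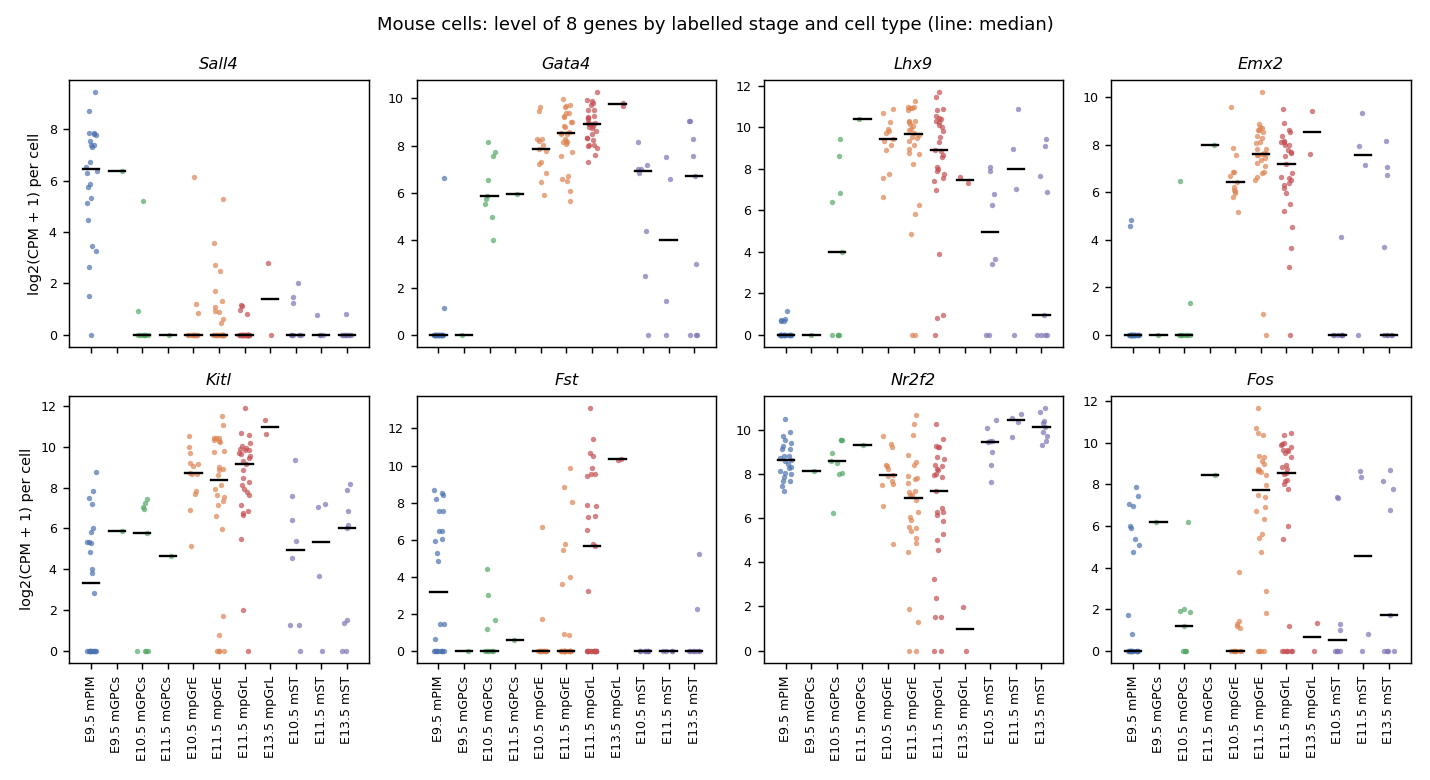
CPM of 8 genes in each mouse cell, on log2 axes with 1 CPM added, by labelled stage and cell type. Points are cells and lines are medians by group. Sall4 has counts in 23 of 24 E9.5 mPIM cells, Gata4 in 13 of 13 E10.5 mpGrE cells, and Fst in 16 of 29 E11.5 mpGrL cells.

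The comparison of E10.5 mpGrE with E10.5 mGPCs asked how 2 cell types of 1 stage differed. Emx2, a homeobox gene required for the gonad and kidney (Entrez 13797; chromosome 19, 59458690 to 59465357), was at 147 CPM in mpGrE with counts in 13 of 13 cells. It was at 8.75 CPM in mGPCs with counts in 2 of 9, a log2 ratio of 3.92. Pdgfrb, a growth factor receptor of mesenchyme (Entrez 18596; chromosome 18, 61045127 to 61085067), was at 0.580 CPM (0.233 to 1.20) in mpGrE against 128 CPM (120.6 to 136) in mGPCs, a log2 ratio of −6.35. Inhbb, which encodes an inhibin and activin subunit (Entrez 16324; chromosome 1, 119415463 to 119422248), was at 49.1 CPM (45.3 to 53.3) in mpGrE with counts in 8 of 13 cells. It had no count in 9 mGPCs, so it was at least 133-fold higher.

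Genital ridge factors had 7 of 11 higher, 2 lower and a median log2 ratio of 2.27 (random lists, −0.43 to 0.44). Lhx9 was at 786 against 120 CPM, and Nr0b1 at 62.8 CPM in 5 of 13 mpGrE cells against 1 count in mGPCs. Gata4, Nr5a1, Wt1 and Podxl were higher too, and Cbx2 and Cited2 were lower. The pregranulosa list had 4 of 7 higher, 0 lower and a median of 2.56. They were Wnt4 and Rspo1, which encode proteins of WNT signalling (141 against 16.3 CPM and 135 against 18.1 CPM), Kitl, the ligand of KIT (552 against 83.3 CPM), and Amhr2. Amhr2, the receptor of anti-Müllerian hormone, was at 338 against 56.4 CPM. With Inha (143.3 against 6.53 CPM) and Inhbb it made 3 of 5 higher in the list of nuclear receptors and hormone signalling, which had a median of 2.56. The list of coelomic epithelium and mesothelium had a median of 1.60 with 1 of 8 higher, Aldh1a2.

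Genes of epithelial to mesenchymal transition had 6 of 11 lower and a median of −1.52, with Twist1 at 16.1 against 208.95 CPM, Cdh11 at 10.4 against 132 CPM and Snai1 at 13.3 against 106 CPM. Lateral plate mesoderm genes had 4 of 5 lower and a median of −3.72. Hand2, Bmp4, Prrx1 and Isl1 were lower, with Bmp4 at 0.580 against 25.01 CPM, and Gata6 was higher. Gonadal stroma genes had 7 of 15 lower, 1 higher and a median of −0.77, with Col5a2 at 17.2 against 161 CPM and Maf, the gene that was higher, at 92.4 against 12.4 CPM. In the intermediate mesoderm list 4 of 7 were lower and 2 higher, with a median of −2.58. Gata3, Foxc1, Foxc2 and Osr1 were lower and Wt1 and Emx2 were higher. With no filter on low levels that median was 0.084. The retinoic acid list had 4 of 8 lower, 2 higher and a median of −0.90, with Aldh1a1, an enzyme that makes retinoic acid, at 183 against 9.73 CPM and Rarb at 3.07 against 38.3 CPM. G2 and M phase genes had 7 of 12 lower and a median of −1.22, with Aurkb at 74.7 against 315 CPM and Cdk1 at 101.2 against 397 CPM.

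The named genes higher in mpGrE also included Aldh1a7 (279 against 1.23 CPM), Me1 and Prss35, and Sel1l3, Rnf128, Ptprv, Tnfrsf19, Pld1 and Nav2. Rnf128, Ptprv, Tnfrsf19 and Nav2 had no count in mGPCs, and Ptprv, with counts in 12 of 13 mpGrE cells, was at least 214.8-fold higher. The genes lower in mpGrE included Cdh6, a cadherin, and Ednrb, an endothelin receptor, at 134.2 and 101.5 CPM in mGPCs and 1 count each in mpGrE. Adam12, Bend4, Arhgef39 and Gtse1 were lower, and B3galnt1 and Gclc had no count in 13 mpGrE cells. Of the lists of other cell types, endothelium had a median of −2.68 (random lists, −1.32 to 1.26) but none of its 6 measured genes met the rule, and that of nephric duct and mesonephric tubule had a median of −2.81 (random lists, −2.13 to 2.06) with only 1 of 4 lower, Gata3. The mGPCs included cell 9, with 1584 CPM of endothelium genes, and cell 2, with 8310 CPM of red blood cell genes. Without these 2 cells the medians of genital ridge factors and of nuclear receptors and hormone signalling were 1.56 and 2.01. Over all lists 24 of 228 measured genes were higher and 60 lower, where 11.9% of unchanged simulated genes met the rule. All cells of both groups belong to 1 column series. Within the shared code, MS134, 21 list genes were higher and 51 lower, and the medians were 1.53 for genital ridge factors, 2.05 for pregranulosa, 1.92 for nuclear receptors and hormone signalling and −1.76 for lateral plate mesoderm. The log2 ratio of Isl1 was −0.36 within that code.

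The comparison of E11.5 with E10.5 mpGrE cells asked how 1 cell type differed between stages. Runx1, a transcription factor of early pregranulosa cells (Entrez 12394; chromosome 16, 92601466 to 92826074), was at 88.6 CPM at E11.5 with counts in 19 of 28 cells and at 1.66 CPM at E10.5 with counts in 3 of 13, a log2 ratio of 5.07. Sox9, a transcription factor of Sertoli cells and cartilage (Entrez 20682; chromosome 11, 112782210 to 112787757), was at 5.55 CPM (4.85 to 6.31) at E11.5 against 171 CPM (164 to 178) at E10.5, a log2 ratio of −4.71. Fos, an immediate early gene (Entrez 14281; chromosome 12, 85473890 to 85477274), was at 513 CPM (506 to 519.6) against 1.16 CPM (0.634 to 1.95), a log2 ratio of 7.89.

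The pregranulosa list had 4 of 11 higher at E11.5, 0 lower and a median of 2.82 (random lists, −0.49 to 0.52). Runx1, Bmp2 (96.6 against 7.87 CPM), Axin2 and Msx1 were higher. The WNT response list had 3 of 8 higher and a median of 2.31. They were Axin2 (30.6 against 3.48 CPM), Sp5 and Nkd1, and Lgr5, a receptor of R-spondins, had counts in 6 of 28 cells at E11.5 and in 0 of 13 at E10.5. The dissociation stress list had 5 of 12 higher, 0 lower and a median of 2.92, namely Fos, Fosb, Junb, Egr1 and Ier2. Egr1 was at 237.4 CPM with counts in 20 of 28 cells against 1 count at E10.5, and Fosb was at 101.7 CPM against 1 count. The summed level of this list per cell was higher at E11.5 in mST cells too, with a median of 1500 against 316 CPM.

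Gonadal stroma genes had 3 of 15 higher, 5 lower and a median of −0.57. The higher genes included Wnt5a (182 against 32.3 CPM) and Pdgfra, and the lower genes included Postn (19.5 against 108 CPM), Nr2f1, Col1a2 and Ptn. The red blood cell list had 3 of 6 lower and a median of −2.10, with Hbb-bs at 17.4 against 106 CPM and Hba-a1 at 8.62 against 50.3 CPM. Reads of these globin genes may be shared with near-identical copies. Imprinted genes had 4 of 13 lower, Meg3, Dlk1, Cdkn1c and Plagl1, with Plagl1 at 23.04 against 178 CPM, and a median of −0.17. The FGF response list had a median of 1.15 with Fgfr2 higher (130.5 against 36.9 CPM) and Fgfr1 lower. The S phase list had a median of 0.49 and no member that met the rule.

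Itga6, an integrin (400 against 7.37 CPM), Kctd14 (1047 against 41.4 CPM), Tulp2, C1qtnf7, Pole and Syngr2 were also higher at E11.5. Gas6, a ligand of TAM receptors, and Tex15 had no count in 13 E10.5 cells and were at least 509-fold and 403-fold higher. Cxcl12, a chemokine, was at 44.9 CPM against 578 CPM with counts in 13 of 13 E10.5 cells, and Chchd10, Cbln1, Capn6, Dennd4b, Adcyap1r1 and Crispld2 were lower too. Over all lists 25 of 226 measured genes were higher and 20 lower, where 6.11% of unchanged simulated genes met the rule. The E11.5 cells included cell 13, with 3025 CPM of endothelium genes, and without it 24 list genes were higher and 20 lower. No label code or column series holds cells of both stages, so stage cannot be told apart from either, and without the 14 E11.5 cells of the series that held 1 mpGrL cell 38 list genes were higher. The pregranulosa median was 0.20 without those cells, inside the range of random lists, and 2.56 without the other series. The medians of the WNT response, gonadal stroma and imprinted genes were 2.44, −2.01 and −0.65 without those cells and 1.09, −0.021 and 0.13 without the other series. With a code or series left out, the medians of the FGF response and of S phase reached 0.85 and 0.32, inside the range of random lists.

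The comparison of E11.5 mpGrL with E11.5 mpGrE asked how 2 cell types of the E11.5 ovary differed, and cell cycle genes differed most. Aspm, a spindle protein (Entrez 12316; chromosome 1, 139454188 to 139494088), was at 105.35 CPM (102.2 to 109) in mpGrE with counts in 19 of 28 cells. It had no count in 29 mpGrL cells, so it was at least 974-fold lower. All 12 measured genes of G2 and M phase were lower in mpGrL, with a median log2 ratio of −3.59 (random lists, −0.46 to 0.36). Tpx2 was at 0.685 against 104.3 CPM, Ccnb1, a mitotic cyclin, at 4.76 against 176 CPM and Ube2c at 15.4 against 464 CPM. Of 12 measured S phase genes 8 were lower, with a median of −1.51, among them Cdc6 (4.91 against 122.3 CPM), Ccne1 (3.72 against 35.6 CPM) and Rrm2 (42.2 against 206 CPM). The remaining named genes lower in mpGrL were Ccna2, Ect2, Cit, Casc5, Ckap2l, Cenpm and Bub1, which take part in mitosis.

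Over all lists 3 of 230 measured genes were higher in mpGrL and 33 lower. The 3 were Fst, which encodes the activin-binding protein follistatin (Entrez 14313; chromosome 13, 114452262 to 114458989), Wnt4 and Cdkn1a. Fst was at 818 against 61.1 CPM with counts in 16 of 29 against 9 of 28 cells, a log2 ratio of 3.72. Cdkn1a, an inhibitor of cyclin-dependent kinases, was at 438 against 72.9 CPM, and the cell cycle inhibitor list had a median of 0.72. The pregranulosa list had a median of 0.89 (random lists, −0.38 to 0.36). Foxl2, a transcription factor of granulosa cells, had counts in 6 of 29 mpGrL cells and 1 of 28 mpGrE cells and did not meet the rule. Mxd4, a repressor of MYC targets (Entrez 17122; chromosome 5, 34176580 to 34187710), was the 1 gene that met the stricter rule for named genes, at 223 CPM (217.9 to 229) against 69.6 CPM (67.1 to 72.2) with counts in 29 of 29 mpGrL cells. The list of coelomic epithelium and mesothelium had a median of −0.77 with no member that met the rule.

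The 2 E11.5 column series split these groups unequally, with 28 mpGrL and 14 mpGrE cells in 1 series and 1 and 14 in the other. Within the first series 12 list genes were higher and 36 lower, the G2 and M phase median was −4.22, the pregranulosa median was 1.22, and the log2 ratio of Fst was 7.13 and of Mxd4 2.58. Within the 3 label codes that hold at least 2 cells of each group, 16 list genes were higher and the G2 and M phase median was −5.99. The count of higher genes was 5 to 9 without code MS116, MS117, MS130, MS132, MS152 or MS155. The medians of the gonadal stroma list (−0.54, with Tcf21 lower) and of the retinoic acid list (−0.92) turned to 0.19 and 0.26 within that series. The stroma median was 0.027 within codes and 0.41 without code MS155. With a code or series left out, the medians of cell cycle inhibitors and of coelomic epithelium and mesothelium reached 0.36 and −0.52, inside the range of random lists. Of unchanged simulated genes 2.15% met the rule. Without mpGrE cell 13, which held 3025 CPM of endothelium genes, 4 list genes were higher and 34 lower.

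The comparison of E10.5 mST with E10.5 mpGrE asked how a further cell type of that stage differed. Foxp2, a forkhead transcription factor (Entrez 114142; chromosome 6, 14901349 to 15441977), was at 345 CPM (329.9 to 360.3) in mST with counts in 8 of 8 cells against 3.73 CPM (2.72 to 4.99) in mpGrE, a log2 ratio of 6.19. Twist1, a transcription factor of mesenchyme (Entrez 22160; chromosome 12, 33957671 to 33959831), was at 306 against 16.1 CPM, a log2 ratio of 4.17. Emx2 had counts in 1 of 8 mST cells against 13 of 13 mpGrE cells, and was at 2.07 against 147 CPM.

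Genes of epithelial to mesenchymal transition had 9 of 11 higher in mST, 0 lower and a median of 1.78 (random lists, −0.52 to 0.50), with Cdh11 at 269.3 against 10.4 CPM and Zeb2 at 484 against 41.8 CPM. Gonadal stroma genes had 7 of 16 higher, 1 lower and a median of 1.31. Nr2f1, Nr2f2, Pdgfra, Pdgfrb (54.5 against 0.580 CPM) and 3 collagen genes were higher, with Col1a1 at 388 against 71.5 CPM. The posterior Hox list had 7 of 10 higher, 0 lower and a median of 1.64, with Hoxa9 at 37.1 against 2.32 CPM and Hoxc9 at 26.6 against 1.41 CPM. FGF response genes had 3 of 6 higher and a median of 2.09, with Fgfr2 at 283 against 36.9 CPM. Imprinted genes had 3 of 13 higher and a median of 0.80, with Igf2r at 1.45 and Ndn at 1.11. The intermediate mesoderm list had a median of 2.82 with Foxc1 and Foxc2 higher (Foxc2 at 123.98 against 3.07 CPM) and Wt1 and Emx2 lower. With no filter on low levels that median was −0.053.

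G2 and M phase genes had 11 of 12 lower in mST and a median of −3.30, with Bub1 at 2.41 against 84.4 CPM. The cell cycle inhibitor list had 2 of 5 lower and a median of −3.36, with Btg1 at 18.6 against 200.3 CPM. Genital ridge factors had 7 of 12 lower, 2 higher and a median of −1.45, with Lhx9 at 93.6 against 786 CPM. The pregranulosa list had 3 of 6 lower and a median of −2.62, namely Rspo1 (0.690 against 135 CPM), Kitl and Amhr2. The list of coelomic epithelium and mesothelium had 3 of 8 lower and a median of −2.35, and Pard6b, a cell polarity protein, had no count in 8 mST cells and was at least 58.6-fold lower. In the list of nuclear receptors and hormone signalling Inhbb, Inha (18.3 against 143.3 CPM) and Amhr2 (62.1 against 338 CPM) were lower and Nr2f2 was higher, with a median of −2.43. Its median was −3.06 to −0.22 over all settings tried, and −0.22 lies inside the range of random lists (−0.99 to 0.97).

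Epha4, an ephrin receptor (136 against 0.580 CPM), Bmp5 (99.3 against 0.746 CPM), Slc8a1, Svep1, Nacc2, Garnl3, Col25a1, Bbs7 and Fads3 were also higher in mST. Abtb2, Stk26, Gpr56, Ccna2, Fzd5, Rnf128, Ptprv, Pnlip and Cep85 had no count in 8 mST cells. Abtb2 was at least 258-fold lower and Cep85 at least 133.9-fold lower, and Eif1a had 1 count in mST. The list of nephric duct and mesonephric tubule had a median of 3.18 (random lists, −3.59 to 3.16) with no member of 4 that met the rule. Over all lists 49 of 224 measured genes were higher and 45 lower, where 13.6% of unchanged simulated genes met the rule. Both groups belong to 1 column series, and mST cell 1 held 1674 CPM of red blood cell genes. Within code MS134 45 list genes were higher and 55 lower, and the medians were 0.72 for the FGF response, inside the range of random lists, 1.85 for intermediate mesoderm, −5.25 for coelomic epithelium and mesothelium and −4.15 for G2 and M phase genes.

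The comparison of E11.5 mST with E11.5 mpGrE rests on 4 mST cells. One of them, cell 2, held 1602 CPM of genes of nephric duct and mesonephric tubule, against at most 1.43 CPM in the others. It is also the deepest of the 4. Hic1, a transcriptional repressor of mesenchymal cells (Entrez 15248; chromosome 11, 75161377 to 75170255), was at 123 CPM (113.8 to 132) with counts in 4 of 4 mST cells and at 0.606 CPM (0.392 to 0.894) with counts in 3 of 28 mpGrE cells, a log2 ratio of 6.27. Nr2f2, a nuclear receptor of stromal cells, was at 1410 against 257 CPM with counts in 4 of 4 mST cells. Runx1 had no count in 4 mST cells and was at least 172-fold lower than its 88.6 CPM in mpGrE.

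Gonadal stroma genes had 9 of 16 higher in mST, 0 lower and a median of 1.15 (random lists, −0.52 to 0.79). Col1a1 was at 316 against 39.4 CPM and Ptn at 432 against 52.7 CPM. Genes of epithelial to mesenchymal transition had 5 of 10 higher, 1 lower and a median of 1.26, with Snai1 at 265.96 against 14.1 CPM and Mmp2 at 443 against 136 CPM, and Cdh2 was lower. The pregranulosa list had 6 of 11 lower, 0 higher and a median of −3.49, with Msx1 at 1.20 against 304 CPM and Fst at no count in 4 mST cells against 61.1 CPM. Genital ridge factors had 6 of 12 lower, 1 higher and a median of −0.94, with Cited2 at 5.82 against 91.8 CPM. Glycolysis genes had 11 of 14 lower and a median of −2.57, with Tpi1 at 39.7 against 506 CPM. G2 and M phase genes had 7 of 12 lower and a median of −1.32, with Cenpe at 2.74 against 206 CPM. In the list of nuclear receptors and hormone signalling 4 of 5 were lower, with Inhbb at 4.11 against 86.6 CPM and a median of −2.28. The retinoic acid list had 2 of 6 lower, Aldh1a1 and Crabp2, 1 higher and a median of −3.67. Its median was −4.64 to −1.32 over all settings tried, and −1.32 lies inside the range of random lists (−2.65 to 1.20).

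Prickle2, Mamld1, Islr, Plag1, Ccdc126, Snx32 and Tmem45a were also higher in mST, at 112.2 CPM (Plag1) to 259.8 CPM (Ccdc126). Kctd14, Itga6 and Rgs2, at 1047, 400 and 356 CPM in mpGrE, had 1 count each in mST. Ccnjl, Pank1, Etfa, Fmnl2, Naaa, Nfe2l2 and Il6st had none, and Ccnjl was at least 513-fold and Il6st at least 420.1-fold lower. Over all lists 31 of 224 measured genes were higher and 65 lower, where 20.3% of unchanged simulated genes met the rule. Lists of 12 genes set to a 2-fold change were not recovered in that simulation. The median log2 ratio of all measured genes was −0.55, and the 4 mST cells had a median of 4817.5 genes after thinning against 6649. Without mpGrE cell 13, which held 3025 CPM of endothelium genes, 31 list genes were higher and 66 lower. Within the column series of the mST cells 38 list genes were higher and 69 lower, with medians of 2.47 for stroma, −1.42 for pregranulosa and −1.84 for G2 and M phase genes. Within the 1 label code with at least 2 cells of each group the medians of pregranulosa genes and of nuclear receptors and hormone signalling were both −0.92 and that of epithelial to mesenchymal transition was 0.98, all inside the range of random lists. The shared value of −0.92 is that of Amhr2, the only gene in both lists. The log2 ratio of Fst was 0 and that of Cited2 was −0.79 within that code. For Fst this means no count in either the 2 mST or the 7 mpGrE cells of the code. Without code MS116, which holds mST cells 2 and 4, the log2 ratio of Ptn was −0.74 and that of Mmp2 was −0.11. The median of epithelial to mesenchymal transition was then 0.76, inside the range of random lists, and that of S phase, −0.77 over all cells, was 0.58. Without the deepest cell of each group, which leaves out mST cell 2, the log2 ratio of Ptn was −0.039 and the S phase median 0.064.

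The comparison of E13.5 with E10.5 mST cells asked how cells of that label differed between stages. Tbx18, a T-box factor of urogenital mesenchyme (Entrez 76365; chromosome 9, 87702800 to 87731260), was at 508 CPM (489 to 526) at E10.5 with counts in 7 of 8 cells and at 0.325 CPM (0.0669 to 0.949) at E13.5 from 3 counts in 9 cells. Foxc2, a forkhead factor of mesoderm (Entrez 14234; chromosome 8, 121116171 to 121118895), had no count in 9 E13.5 cells and was at least 382-fold lower than its 123.98 CPM at E10.5. Hic1 had no count in 8 E10.5 cells and was at least 534-fold higher at E13.5, where it was at 276 CPM (265.8 to 287) with counts in 8 of 9 cells.

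Gonadal stroma genes had 8 of 17 higher at E13.5, 1 lower and a median of 1.44 (random lists, −0.48 to 0.50). Tcf21, Pdgfra, Pdgfrb, Wnt5a, Dcn and Col1a1 were among the higher genes, and Nr2f1, an orphan nuclear receptor, was lower at 69.4 against 1721 CPM. Extracellular matrix genes had 6 of 15 higher, 1 lower and a median of 0.89, with Bgn at 545 against 66.2 CPM, Fbn1 at 172 against 24.3 CPM and Col6a1 at 147 against 34.1 CPM. G2 and M phase genes had 8 of 12 higher, 0 lower and a median of 4.19, with Cdk1 at 234 against 4.14 CPM and Aurka at 86.8 against 0.690 CPM. Genital ridge factors had 3 of 12 higher, Emx2, Wt1 and Tcf21, 1 lower, Cited2, and a median of 0.91. The pregranulosa list had 2 of 6 higher, Wnt4 (173 against 19.3 CPM) and Axin2, and a median of 1.91 (random lists, −1.70 to 1.57). With 1 label code left out the pregranulosa median was 0.72 to 4.01, lowest without MS116, and the genital ridge median 0.49 to 1.35, lowest without MS132, so that both fell inside the range of random lists.

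Imprinted genes had 7 of 13 lower, 0 higher and a median of −1.13, with Peg10 at 0.433 against 40.01 CPM, Cdkn1c at 33.6 against 466 CPM and Igf2r at 67.8 against 277 CPM. In the intermediate mesoderm list Foxc1 (3.79 against 373 CPM) and Foxc2 were lower and Wt1 and Emx2 higher, with a median of −3.46. This median varied from −5.31 to −0.99 over all settings tried, and −0.99 lies inside the range of random lists (−1.74 to 1.37). The dissociation stress list had Egr1 and Junb higher, Dusp1 lower and a median of 0.91, inside the range of random lists. Egr1 (Entrez 13653; chromosome 18, 34861207 to 34864956) had no count in 8 E10.5 cells and was at least 654-fold higher.

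Col6a3, Itga8, Cenpf (802 against 2.41 CPM), Sgol2a, Plxnc1, Cacna1g, Tbx2 and Anln were also higher at E13.5, and Cacna1g, a calcium channel, had counts in 9 of 9 cells against 0 of 8. Clstn2, Mc2r, Fam19a2, Kit, Gfra3, Fhl1, Kcnq5 and Epha4 were lower. Kit, the receptor of KIT ligand, and Mc2r, the receptor of ACTH, had no count at E13.5 and were at least 589-fold and 679-fold lower. Over all lists 44 of 233 measured genes were higher and 43 lower, where 18.6% of unchanged simulated genes met the rule. Scaling by TMM or DESeq2 size factors shifted all log2 ratios by 0.12. No label code or column series holds cells of both stages, so these cannot be told apart from stage. Without code MS116 the log2 ratio of Emx2 was −1.62. Red blood cell genes differed too, with 3 of 5 lower at E13.5, Hba-a1, Hba-a2 and Hbb-bs, and a median of −2.79 (random lists, −3.13 to 2.79). The E10.5 mST cell 1 held 1674 CPM of them, and without it the median of red blood cells was −1.67 and that of gonadal stroma 1.47.

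The comparison of 2 cPGCs with 22 cGPCs of the E36 monkey genital ridge asked how these cell types differed. NANOG, a pluripotency factor (Entrez 102114964), was at 1395 CPM (1358 to 1431) in cPGCs and at 0.0974 CPM (0.0118 to 0.352) in cGPCs, from 2 counts. POU5F1, another pluripotency factor (Entrez 102115117), was at 2059 CPM (2015 to 2104) with counts in both cPGCs against 5.70 CPM (4.71 to 6.83) with counts in 12 of 22 cGPCs, a log2 ratio of 8.26. NR2F2 (Entrez 102119390) was at 1227 CPM (1212 to 1243) with counts in 22 of 22 cGPCs against 3 counts in cPGCs. WT1, a transcription factor of the genital ridge (Entrez 102131274), was at 708 CPM (697 to 719.8) in cGPCs against 1 count in cPGCs.

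Germ cell genes had 11 of 12 higher in cPGCs, 0 lower and a median of 6.30 (random lists, −1.76 to 1.05). Among them SOX17 was at 245 CPM against 3 counts, and DPPA3, NANOS3, DND1, DDX4, TFAP2C, PRDM1, SALL4 and KIT were higher. The pluripotency and reprogramming list had 5 of 8 higher and a median of 3.16, with KLF4 at 269.8 against 0.341 CPM and SALL4 at 175 against 0.390 CPM. FGF response genes had 4 of 7 higher, 1 lower and a median of 1.90, with ETV4 at 161.8 against 9.26 CPM and FGFR1 at 117 against 1484 CPM.

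Genital ridge factors had 9 of 13 lower in cPGCs, 1 higher, LHX2, and a median of −4.81, or −5.18 with genes at 0 set to their floor. LHX9 and NR0B1 had counts in 15 and 12 of 22 cGPCs and no count in 2 cPGCs. By the floor of 3 counts they were at least 408-fold and 341-fold lower, which does not cover the spread between cells. Gonadal stroma genes had 7 of 15 lower and a median of −4.99, or −5.30 with genes at 0 at their floor. They included COL1A2 and COL3A1, at 287 and 295 CPM in cGPCs against 1 and 2 counts in cPGCs. In the list of nuclear receptors and hormone signalling 3 of 5 were lower, with a median of −5.51, or −5.91 at the floor, and AMHR2 was at least 344-fold lower. The retinoic acid list had 4 of 5 lower and a median of −5.18, or −5.56 at the floor. ALDH1A2, an enzyme that makes retinoic acid, had counts in 14 of 22 cGPCs and was at least 206-fold lower by the same floor. ALDH1A1 was higher. Imprinted genes had 5 of 10 lower and a median of −2.18, with PLAGL1 at 13.9 against 669 CPM. Over all settings tried, the highest medians of 4 of these lists lay inside the range of random lists. They were −1.39 for gonadal stroma (−1.98 to 0.97) and −1.84 for nuclear receptors and hormone signalling (−3.67 to 1.84). For retinoic acid it was −1.92 (−3.90 to 1.82) and for imprinted genes −0.75 (−1.36 to 1.01). That of genital ridge factors, −2.06, lay below its range (−1.43 to 0.98).

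ACTG2 (1517 against 0.926 CPM), TCL1B, L1TD1, LIN28A, AP3B2, MYOF and NLRP2 were also higher in cPGCs, and DCAF4L2 had no count in 22 cGPCs and was at least 2510.3-fold higher. MBNL3, a splicing regulator, had no count in cPGCs and was at least 1784-fold lower than its 1328 CPM in cGPCs. HIP1, ZFP36L1 (19.1 against 2130.1 CPM), ADGRL1, PRDX2, PTOV1, STMN1 and MARCKSL1 were lower too. Over all lists 42 of 196 measured genes were higher and 50 lower, where 36.2% of unchanged simulated genes met the rule, so the counts of single genes here say little. Lists of 12 genes set to a 2-fold change were not recovered in that simulation. The cPGCs had a median of 7821 genes after thinning against 4556 in cGPCs, and the median log2 ratio of all measured genes was −0.34. Within the 1 shared code, with 2 cells of each group, 75 list genes were higher and 39 lower, and the medians were 6.03 for germ cell genes, −2.22 for genital ridge factors and 0.24 for the FGF response, the last inside the range of random lists. Within that code the log2 ratios of ALDH1A2 and NR0B1 were 0 and that of COL1A2 was −0.33. Neither ALDH1A2 nor NR0B1 had a count in cPGCs, so a ratio of 0 means that the 2 cGPCs of the code had none either. Over all cGPCs these genes had counts in 14 and 12 of 22 cells. Levels this low in 2 cells of each group cannot show whether these genes differ between cells that share a code. Without the column series that holds cGPCs alone the germ cell median was 6.91, the genital ridge median −4.50 and the FGF response median 1.10.

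The mouse groups were ranked by the correlation of their levels with those of the monkey cGPCs. Of 14775 genes of the same symbol, the 2000 that varied most between these mouse groups were used, so the pools ranked also chose the genes. Spearman's rho was 0.408 for E9.5 mPIM, 0.401 for E11.5 mpGrE, 0.387 for E10.5 mpGrE and 0.360 for E10.5 mGPCs. It was 0.296 for E11.5 mpGrL, 0.263 for E10.5 mST, 0.243 for E13.5 mST and 0.0495 for E11.5 mST. These are correlations across genes of 1 pool per group, and genes are not independent replicates. The group ranked first depended on the setting, since E10.5 mGPCs led with the 500 most variable genes (0.384 against 0.374 for E9.5 mPIM) and E11.5 mpGrE led with the mean over cells of log levels (0.473 against 0.395). E11.5 mST ranked last in every setting, but the size of its rho varied. It was 0.0456 with RPM values, 0.0691 with 500 genes and 0.190 with mean log levels. Over all genes of at least 5 CPM it was 0.405, against 0.530 for E9.5 mPIM.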

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

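The tests of technical explanations in this part were all chosen after the results were seen. Extreme cells were looked for in 11 measures of the 4 groups of 4 to 10 cells, 44 in all, and 6 stood apart. The cut-offs are those that chance passes in about 1 in 20 cases where values are normally distributed. Several sums lay at or near 0 in most cells, where that share need not hold, and the measures are not independent of one another. The 6 of 44 are thus not set against chance. E10.5 mGPCs cell 1 held 49.9 CPM of white blood cell genes, against 0 to 4.84 CPM in the other cells of its group. E10.5 mST cell 7 held 4.77 CPM of G2 and M phase genes, against 145 to 860 CPM. E11.5 mST cell 4 held 59.8 CPM of white blood cell genes, against 0 to 0.396 CPM, and E11.5 mST cell 2 held 1602 CPM of genes of nephric duct and mesonephric tubule, against 0 to 1.43 CPM. E13.5 mST cell 1 held 79.9 CPM of white blood cell genes, against 0 to 4.66 CPM. E13.5 mST cell 9 held 15.1 CPM of dissociation stress genes, against 196 to 2251 CPM. Larger groups were not searched, and in E11.5 mpGrE cell 13 held 3025 CPM of endothelium genes. Cells outside the comparisons also gave signal above the floor of 3 counts. The 2 E13.5 mpGrL cells held 8013 CPM of pregranulosa genes (floor 1.59 CPM), the E9.5 mGPCs cell held 4088 CPM of gonadal stroma genes (floor 2.68 CPM) and the E11.5 mGPCs cell held 6892 CPM of them (floor 1.42 CPM).

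Of 12 measured dissociation stress genes 5 were higher in E11.5 than in E10.5 mpGrE cells. If the handling of 1 of the 2 E11.5 column series were the cause, the other series should lie near E10.5, and the tables argue against that. The series with the lower median still had a list median of 2.39, above all random lists, and the other had 2.52. Handling that differed between the stages cannot be told apart from stage, since 0 label codes or column series hold cells of both groups. A biological difference between the stages stays open too and was not tested.

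Cell cycle genes were lower in E11.5 mpGrL than in E11.5 mpGrE cells. Fewer counts per mpGrL cell are argued against, since at 1 depth the median of the G2 and M phase list was −3.62, where level-matched random lists gave −0.41 to 0.33. The median was −3.59 before thinning, and a ratio of pooled CPM depends little on depth in any case. Thinning did not make the detected genes equal, with medians of 5608 in mpGrL against 6649 in mpGrE. Fewer detected genes per mpGrL cell was therefore not tested and stays open. Unequal shares of the 2 column series are argued against as well, since within the series that holds 28 mpGrL and 14 mpGrE cells the median was −4.22. A difference between the cell types in the share of dividing cells may be real, as a hypothesis found and tested on the same cells. Assignment of cells to types by these very genes stays open, because the labels do not give the method.

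The endothelium list had a median log2 ratio of 4.39 in E10.5 mGPCs against E9.5 mPIM cells, although only 1 of its 5 measured genes, Egfl7, met the rule for a higher gene. Cell 9 of the mGPCs held 91.8% of the counts of the list, with 1584 CPM against at most 90.998 CPM in the others, and without it 3 genes were measured, too few for a median. Were that cell an endothelial cell with no RNA of mGPCs, its gonadal stroma genes should lie far below those of the other 8 cells, and at 4343 CPM they lay within the range of 664 to 6211 CPM. A pair of cells caught together, or free RNA of another cell, stays open, and its total of 1861068 counts was the highest of the 9 (next, 1141188).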

How the results depend on the processing

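Leaving out each column series, or the 4 cells rich in endothelium or red blood cell genes, was chosen after the data were seen, and the other alternatives were planned. No paired analysis was possible because the labels name no animals. Of 320 recomputed counts of higher or lower list genes 285 stayed within 1.5 times the reported count, and of 6880 recomputed values of 348 pairs of a gene and a comparison 26 changed sign, 6 of them of pairs that met the naming or list rule. The rules on level, AUC and size leave the log2 ratio of a gene as it is, and another pseudocount cannot change its sign. Named genes were also chosen for 1 direction within shared codes. For E10.5 mpGrE and E10.5 mST the runs within codes and without MS155 hold the same cells. The low share of sign changes is thus in part built in and does not measure robustness. Of 3926 recomputed list medians 257 changed sign, 14 of them of lists outside the range of random lists. Leaving out the 4 cells moved no count by that much. With no AUC rule the counts were 61 higher and 49 lower for E10.5 mGPCs against E9.5 mPIM, 43 higher for E10.5 mpGrE against mGPCs, 61 higher for E11.5 against E10.5 mpGrE, 24 higher and 70 lower for E11.5 mpGrL against mpGrE, 71 lower for E10.5 mST, 53 higher for E11.5 mST, 81 higher for E13.5 mST and about 1.1e2 lower for cPGCs. With a log2 ratio of at least 2 they were 25 and 19, 32 lower, 10 lower, 18 lower, 24 and 28 (E10.5 mST), 17 higher and 26 lower in the same order, the last for E13.5 mST. Both follow from the rule, which admits more or fewer genes. Within label codes there were 47 lower for E10.5 mGPCs, 16 higher for mpGrL and 75 higher for cPGCs. With the mean over cells of log levels there were 33 lower for E11.5 mpGrE, 6 higher for mpGrL and 75 higher for cPGCs. For mpGrL RPM values gave 7 higher, and leaving out the deepest cells 6. The correlation of cGPCs with E9.5 mPIM was 0.374 with 500 genes, 0.530 with all genes of at least 5 CPM, 0.395 with mean log levels and 0.446 with RPM. Apart from the AUC and log2 rules the cause was not tested.

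With each label code or column series left out in turn, the higher and lower list genes numbered 37 to 46 and 25 to 37 for E10.5 mGPCs against E9.5 mPIM, 25 to 38 and 18 to 28 for E11.5 against E10.5 mpGrE, 4 to 12 and 30 to 48 for mpGrL against mpGrE, 29 to 38 and 63 to 85 for E11.5 mST, 40 to 52 and 41 to 51 for E13.5 mST, and 44 to 59 and 48 to 55 for cPGCs. For mpGrL there were 5 higher without MS116, 6 without MS117, MS130, MS132 or MS155, 9 without MS152 and 12 without the series of 1 mpGrL cell. That series left out gave 38 higher for E11.5 mpGrE.

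The changes of sign of genes that met a rule and of lists outside the random range were as follows, and the others are not listed. In E10.5 mGPCs against E9.5 mPIM Nr5a1 (−0.050) and Twist1 (−0.94) turned without MS134, with ranges of −0.050 to 5.22 and −0.94 to 3.16 over the codes and series left out. The median of cell cycle inhibitors there (1.11) was −0.44 to 2.10, lowest without MS155. With no filter the intermediate mesoderm median was 0.084 for E10.5 mpGrE and −0.053 for E10.5 mST. For mpGrL the stroma median was 0.027 within codes, and −1.19 to 0.41 with codes or series left out, with 0.41 without MS155 and 0.19 without the smaller series. Its retinoic acid median was −1.47 to 0.26, highest without that series. For E11.5 mST, leaving out the deepest cells gave −0.58 for intermediate mesoderm, 0.064 for S phase and −0.039 for Ptn. Without MS116 these were −1.47, 0.58 and −0.74, and Mmp2 was −0.11, with ranges of −1.47 to 1.64, −4.86 to 0.58, −0.74 to 3.86 and −0.11 to 2.07. For E13.5 mST the retinoic acid median was 0.44 without the deepest cells and −3.36 to 0.26 over the codes, highest without MS134. Emx2 was −1.62 to 5.77, lowest without MS116, and the median of nuclear receptors and hormone signalling was −0.24 to 4.15, lowest without MS132. With a code or series left out, other medians described in the report entered the main range of random lists, which was drawn for all cells. They reached 0.20 (pregranulosa), −0.021 (stroma), 0.85 (FGF response) and 0.32 (S phase) for E11.5 mpGrE, 0.36 (cell cycle inhibitors) and −0.52 (coelomic epithelium) for mpGrL, 0.72 (FGF response) for E10.5 mST, 0.76 (epithelial to mesenchymal transition) and −1.42 (nuclear receptors) for E11.5 mST, 0.49 (genital ridge) and 0.72 (pregranulosa) for E13.5 mST and 1.10 (FGF response) for cPGCs. For E10.5 mGPCs they reached 0.44 (epithelial to mesenchymal transition), 0.43 (BMP response), 0.34 (extracellular matrix), 0.13 (imprinted) and −0.94 (WNT response). Other settings, with no single code or series left out, also brought medians into the range of random lists. Among these were −0.14 (posterior Hox) for E10.5 mGPCs and 0.22 (nuclear receptors) for E10.5 mpGrE. For E10.5 mST they were −0.22 (nuclear receptors) and −0.62 (cell cycle inhibitors). Further values were −1.32 (retinoic acid) for E11.5 mST and −0.99 (intermediate mesoderm) for E13.5 mST. For cPGCs they were −1.39 (stroma), −1.84 (nuclear receptors), −1.92 (retinoic acid) and −0.75 (imprinted). The red blood cell median of E10.5 mGPCs was 1.01 to 4.33, lowest without MS155. The cause was not tested. Within-code values were not run for E11.5 against E10.5 mpGrE and E13.5 against E10.5 mST, which share no code, and the deepest cells of cPGCs against cGPCs were not left out, as 1 cPGCs cell would remain. Depth limits genes at 0 to the floor of 3 counts per group, 0.0727 CPM in E11.5 mpGrE and 0.745 CPM in cPGCs.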

Other observations

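No test was made in this part, and the values below were chosen after the data were seen. The 2 E13.5 mpGrL cells, which stand outside the comparisons, had counts of 11 of the 15 pregranulosa list genes in both cells and of the other 4, Runx1, Irx5, Msx1 and Nr2f6, in 1 cell. Inhbb and Esr2, of another list, had no count. Fst was at 1296 CPM, Kitl at 1940.0 CPM and Foxl2 at 150.5 CPM, each with counts in 2 of 2 cells. Foxl2 was at 25.1 CPM in E11.5 mpGrL, 4.48 CPM in E11.5 mpGrE and 0 CPM in E10.5 mpGrE. Lgr5 was at 709 CPM in the E13.5 mpGrL cells and at 4.11 CPM in E11.5 mpGrL. Nr2f2 was at 1.06 CPM in E13.5 mpGrL, against 1245 CPM in E13.5 mST. The median of detected genes at 1 depth was 7752.5 in E9.5 mPIM, 6681 in E10.5 mpGrE, 6649 in E11.5 mpGrE, 5608 in E11.5 mpGrL and 4758 in E13.5 mpGrL. In mST it was 6347.5 at E10.5, 4817.5 at E11.5 and 5527 at E13.5.

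The E11.5 mGPCs cell held Lhx9 at 1354 CPM, Tcf21 at 904.5 CPM, Egr1 at 1537 CPM and Gata4 at 60.6 CPM. The E9.5 mGPCs cell held Pdgfra at 403 CPM and Nr2f1 at 1019 CPM, and no count of Gata4, Lhx9 or Nr5a1. Xist, the RNA of the inactive X chromosome, had counts in 24 of 24 E9.5 mPIM cells, 28 of 28 E11.5 mpGrE cells, 27 of 29 E11.5 mpGrL cells and 8 of 9 E13.5 mST cells. Tsix overlaps Xist on the other strand, so their reads are not separated where strand was not used. The monkey cGPCs held WT1 at 708 CPM and GATA4 at 483 CPM with counts in 22 and 21 of 22 cells, and EMX2 at 135 CPM, AMHR2 at 256 CPM and DCN at 436 CPM. SOX9 and FOXL2 had counts in 2 of 22 cGPCs each.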
